A study of Mus musculus with 10 samples.

How the data were processed

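Of the 10 GEO samples, 8 are bulk samples and 2 are single-cell samples. The bulk table holds expected counts per transcript, which per the labels the authors made with Salmon 1.4 on GRCm38 or mm10 before the table was deposited. The index, options and transcript set are not given in the sources used here. No scaling was seen in the values, 83.2% of the positive ones were not whole, and library totals ran from 0.593 M to 38.0 M counts. The single-cell tables hold UMI counts per gene and barcode, which per the labels the authors made from 10x 3' v2 libraries of DAPI-sorted live cells with Cell Ranger and STAR. From the values, every deposited barcode had at least 1004 UMIs, at most 2496 genes and at most 50% mitochondrial UMIs. Raw reads were not used here.

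Of 105833 transcripts 105203 were found in GENCODE M21. The 630 others held 0.213% of counts and were left out. Counts were summed to 33644 genes and rounded, and 64 symbols shared by more than 1 gene ID were kept apart. The table holds 4 numbered columns per bulk sample, which were taken as 4 libraries per group. Column numbers did not pair injured and contralateral kidneys in every arm: the correlation of columns with the same number ran from -0.28 to 0.24 over 12 pairs, with the own number as best match in 6. All 4 pairs of the wild-type tamoxifen arm are among those 6, so a pairing there stays open, and no pairing was used in the main tests. Within groups no library was a copy of another, with a lowest chi-square per gene of 1.561 between thinned libraries. Libraries of different groups were not compared in this way.

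Bulk tests were run with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, 1 coefficient per group over all 8 groups, glmQLFit and quasi-likelihood F tests, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Contrasts averaged the arms with equal weight. EdgeR's lower bound on the p-value at Poisson variance raised values in 469 to 764 genes of the contrasts with uninjured controls and changed the count of injured against uninjured kidneys from 8407 to 8402. With the kidney-profile libraries it lowered contralateral against uninjured kidneys from 71 to 55. Tests, contrasts, gene lists, naming rule and alternatives were fixed before the data were examined, except that nephrectomy against uninjured kidneys was planned as a fold of 1 library against 1 and was tested because 4 libraries each were found. The other priors and CPM minimums foreseen for that fold were therefore not run.

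After the data were seen, further settings were added: fits without the 3 heart-profile libraries, alone and also without CONTRA_TG_VEH library 2 or uninjured library 2, a fit of the 24 libraries of the injury arms alone, a block by column number, and a correction for transcript length. Heart-profile libraries were found by the share of counts from 10 heart genes, 6.33%, 6.34% and 6.20% in those 3, and from 8 kidney genes, at most 0.00344% there, 2.84% to 3.36% in the other libraries of kidneys without ischaemia and 0.696% to 2.75% in injured kidneys. The heart genes were chosen after the libraries were seen. CONTRA_TG_VEH library 2 stood apart with 38.0 M counts, Lrp2 at 2438 CPM and 5.55% mitochondrial counts, and uninjured library 2 held 0.593 M counts.

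Settings fixed beforehand for comparison were RLE factors in the same fit, no low-count filter, the DESeq2 1.42.0 Wald test, each library left out in turn, no arm factor, the intact arms alone and each control arm alone. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists within a contrast. The lists were Hedgehog ligands, Hedgehog response, matrix and myofibroblast, TNF and NF-kB response, tubular injury, proximal tubule, fatty acid oxidation, loop of Henle, distal convoluted tubule, collecting duct, podocyte, endothelial, macrophage, lymphocyte, neutrophil, proliferation, interferon response, cholesterol synthesis, dissociation and immediate early, adipocyte, adrenal cortex, erythroid and sex-linked genes. List genes were also adjusted over the list alone. Log2 values are fitted fold changes with the standard error of the coefficient, and CPM values use library totals.

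Named genes followed a fixed rule. Some genes that the rule picked are not reported here. Ihh, Shh, Dhh, Gli1, Ptch1, Hhip, Tnf, Havcr1, Lcn2, Col1a1 and Acta2 were named wherever measured. Per bulk contrast the 10 genes per direction with the largest log2 fold change were taken among genes past the threshold with a mean log2 CPM of at least 1 and the same direction in every arm or against every comparison library. Where fewer passed, up to 5 more per direction were given by size as values only. From each list the 2 to 4 members with the largest fold were taken. No fold is printed where every library of a comparison group held 0 counts. Il6 was 0 in all 4 uninjured libraries, and so were Ighg1 and the pseudogene Pgam1-ps2.

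Recovery was measured on simulated counts with the depth of these libraries. Per gene, mean and spread were the same in every group apart from the genes changed. No simulated library had a heart profile of its own. The rates with 32 libraries therefore do not describe the real contrasts that hold such libraries. Of genes changed 4-fold the injury test found 90% with 32 and 96% with 29 libraries, and of genes changed 2-fold 67% and 91%. The deletion test in injured kidneys found 70% and 90% at 4-fold and 41% and 67% at 2-fold, the interaction 57% and 81% at 4-fold and 24% and 50% at 2-fold, and nephrectomy against uninjured kidneys 78% and 66% at 4-fold and 35% and 27% at 2-fold. In these simulations false calls were at most 8.4% of calls.

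Single cells were read with scanpy 1.11.5. Barcodes needed at least 200 genes and at most 50% mitochondrial UMIs, which removed none of 3063 injured and 1313 uninjured barcodes, with medians of 2014 and 2391 UMIs, 939 and 981 genes and 5.97% and 23.6% mitochondrial UMIs. Scrublet marked 8 barcodes as doublets, which left 3058 and 1310 cells. Both libraries were log-normalised and clustered together on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, into 20 clusters. A cluster needed at least 3 raised markers of a class, took among such classes the one with most markers in its 10 leading genes and then with most raised markers, and stayed unnamed where another class had more of the 10, which left 3 clusters unnamed. Classes with at least 50 cells in each library were compared by summed UMIs, with a prior of 10 CPM and a minimum of 50 UMIs for naming, leaving out mitochondrial, ribosomal-protein, haemoglobin and class-defining genes. Intervals are exact 95% binomial and Poisson intervals. The principal cell class was also led by the distal genes Calb1 and Slc12a3, and haemoglobin genes were among the leading genes of the intercalated class. List medians were set against 10000 random lists matched on expression. In simulated cells 83.7% of 1500 were named right and 0% wrong, and the intervals held the true ratio in 92% to 100% of genes. Those cells were drawn from the mean profiles of the proximal tubule, loop of Henle, B cell and macrophage classes already named here. They had no free RNA and no spread between cells of a class or between animals. These rates therefore do not describe the naming of the other classes or intervals for real cells. The alternatives were at least 500 genes with at most 20% mitochondrial UMIs, Leiden resolutions 0.5 and 2, doublets kept, and CPM without mitochondrial genes. Genes absent from a deposited table are called not listed, since the tables hold 15340 and 13217 genes. Other tools were anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.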

Results

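Bulk RNA libraries covered 8 groups of mouse kidney with 4 libraries each, and 1 single-cell library each came from an injured and an uninjured kidney. Injured kidneys were taken 2 weeks after 15 minutes of ischaemia. Of the 32 bulk libraries, 3 did not carry a kidney profile. Myh6, the alpha myosin heavy chain of heart muscle, stood at 31550 and 30530 CPM in uninjured control libraries 1 and 4 and at 31040 CPM in nephrectomy library 3. Slc34a1, the phosphate carrier of the proximal tubule, stood at 1.83, 0.92 and 3.70 CPM there. The planned tests kept all 32 libraries, and the number of genes past the threshold in each comparison is followed by the number without those 3, here called the 29 kidney-profile libraries, a setting chosen after the data were seen. P-values cover only the spread between these libraries, because the labels do not say that the 4 columns of a group are separate animals.

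**Figure D1:**
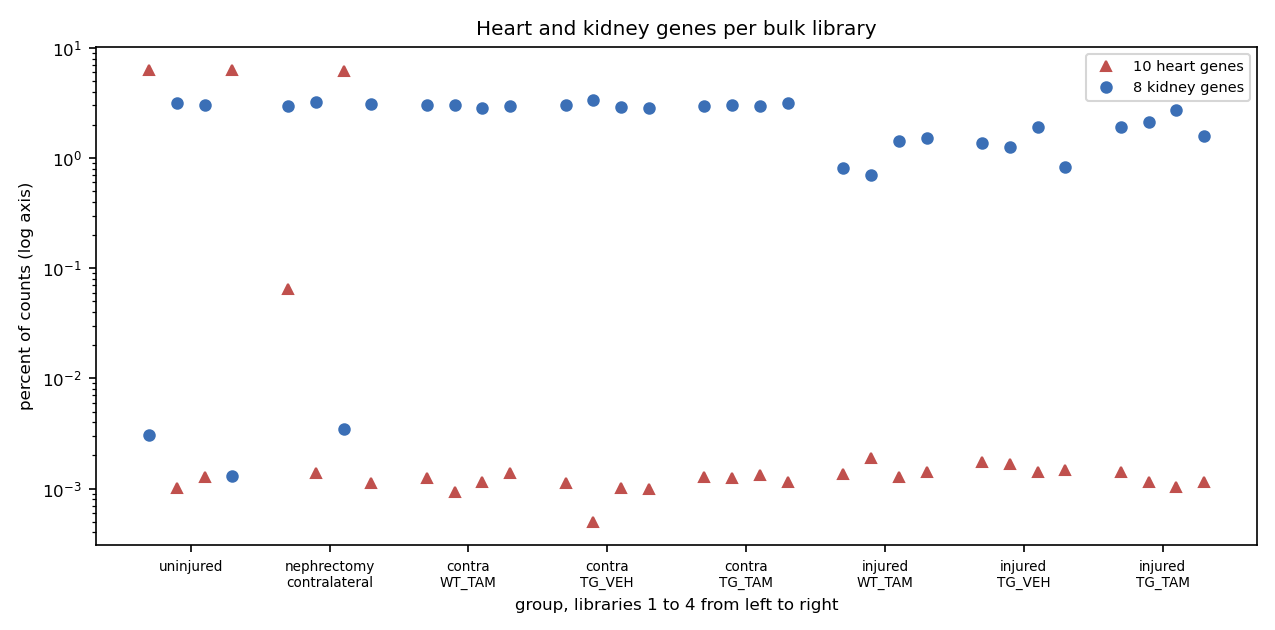
Share of counts from 10 heart genes and 8 kidney genes in each of the 32 bulk libraries. Uninjured control libraries 1 and 4 and nephrectomy library 3 hold heart genes in place of kidney genes.

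Ihh, the ligand deleted by Pax8-driven Cre after tamoxifen, was lower but not absent in the injured kidneys labelled Ihh-deleted. Its values were 4.58, 6.09, 5.09 and 4.86 CPM there, a mean of 5.15 (SD 0.658, n = 4). The injured kidneys of the intact arms held 9.86, 5.99, 9.79 and 11.8 CPM in the wild-type tamoxifen arm and 9.31, 11.2, 15.4 and 6.89 CPM in the floxed vehicle arm, a mean of 10.0 (SD 2.92, n = 8). The labelled-deleted mean was 51.5% of the intact mean, with an exact permutation p = 0.00808 that was chosen after the values were seen. Contralateral kidneys labelled Ihh-deleted held 4.34, 8.69, 3.44 and 17.2 CPM (mean 8.42, SD 6.29) against a mean of 11.2 (SD 2.43, n = 8) in the intact arms, exact p = 0.133. In library 4 of that group Ihh RNA goes against the label, since it exceeded every intact contralateral library. The labels do not say which exons were floxed, and a transcript that lost part of its sequence may still be counted. RNA therefore does not settle whether the gene was deleted. The genome-wide test did not call Ihh, with log2 -0.73 (SE 0.81) in the injured and -0.45 (SE 0.80) in the contralateral kidney. The arms are therefore called labelled Ihh-deleted throughout, and in the contralateral comparison library 2, at 8.69 CPM, also lay inside the intact range of 8.05 to 14.3 CPM, so 2 of its 4 labelled libraries show no reduced Ihh. Ihh stood at 0.210, 5.07, 7.42 and 0 CPM in uninjured controls and at 13.2, 19.0, 0 and 11.1 CPM after nephrectomy, with the low values in the heart-profile libraries. The value of 5.07 CPM rests on few counts, since uninjured library 2 held 0.593 M counts in all.

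Injured kidneys held more RNA of tubular damage, inflammation and scar, and less of proximal transport and fat burning, than contralateral kidneys of the same 3 arms (n = 12 against 12 libraries). Lcn2, the neutrophil gelatinase-associated lipocalin shed by damaged tubules, rose by log2 3.96 (SE 0.29, adjusted p = 1.05e-10). Havcr1, which encodes the injury molecule KIM-1, rose by 1.69 (SE 0.56, adjusted p = 0.0106). Tnf rose by 3.20 (SE 0.45, adjusted p = 1.43e-06), and Col1a1, the main chain of fibrillar collagen, by 2.65 (SE 0.44, adjusted p = 1.45e-05). Acta2, the actin of myofibroblasts, rose by 1.63 (SE 0.35, adjusted p = 0.000299). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10580 of 17208 genes passed an adjusted p of 0.05, of which 5820 rose and 4760 fell. Without the heart-profile libraries 12972 of 17591 passed, of which 6863 rose and 6109 fell.

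Of 11 Hedgehog response genes 6 rose and 1 fell, with the same counts adjusted over the list alone, and the list as a whole did not pass (median 0.82, camera adjusted p = 0.151, adjusted p = 0.34 with an estimated correlation). Gli1, the transcription factor that Hedgehog signalling induces, rose by 2.30 (SE 0.31, adjusted p = 6.92e-07), Gli3 by 1.72 (SE 0.34, adjusted p = 9.88e-05) and Hhip by 1.56 (SE 0.53, adjusted p = 0.0125). Ptch1 stood at -0.24 (SE 0.13, adjusted p = 0.116). Among the ligands Dhh rose by 0.69 (SE 0.26, adjusted p = 0.0245), while Ihh stood at -0.68 (SE 0.53, adjusted p = 0.268) and Shh at 0.79 (SE 0.50, adjusted p = 0.169). Without the heart-profile libraries Ihh fell by -0.70 (adjusted p = 0.00461), Ptch1 by -0.26 (adjusted p = 0.0013), and Shh rose by 0.78 (adjusted p = 0.0262). The injury contrast includes the labelled-deleted arm, with mean Ihh of 5.15 CPM in injured and 8.42 CPM in contralateral kidneys. In the intact arms these means were 10.0 (SD 2.92) and 11.2 (SD 2.43) CPM. The fall of Ihh is therefore not shown for injury alone. Of the 3 ligands 1 rose, also over the list alone (camera adjusted p = 0.836).

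TNF and NF-kB response genes rose. Cxcl2 rose by 5.08 (SE 0.48), Ccl20 by 4.41 (SE 0.56), Cxcl1 by 3.67 (SE 0.49) and Ccl2, the monocyte chemokine, by 3.59 (SE 0.38), and 23 of 24 list genes rose, 23 when adjusted over the list alone (median 2.53, camera adjusted p = 2.9e-17). With an estimated correlation that list had an adjusted p = 0.0483, and it did not pass without the heart-profile libraries, at 0.271. In the tubular injury list 17 of 20 rose, 17 over the list alone, led by the keratins Krt20 at 4.23 (SE 0.52) and Krt19 at 3.54 (SE 0.37) and by the hyaluronan receptor Cd44 at 3.52 (SE 0.42), with adjusted p = 0.0443 with an estimated correlation and 0.271 without the heart-profile libraries. Matrix and myofibroblast genes rose in 33 of 34, and in 34 adjusted over the list alone, with Tnc at 2.88 (SE 0.31), Timp1 at 2.67 (SE 0.42) and Mmp2 at 2.64 (SE 0.59). The matrix list had a camera adjusted p = 1.99e-06, and adjusted p = 0.464 with an estimated correlation.

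Leukocyte genes rose as well. Immunoglobulin genes, products of plasma cells, were among the largest changes: Ighg3 8.01 (SE 0.94), Ighg2c 7.18 (SE 0.99), Ighg2b 7.14 (SE 0.83) and Ighm 6.83 (SE 0.86). The variable segments Igkv1-99 (7.70), Igkv3-5 (7.06), Igkv14-130 (6.97) and Ighv1-5 (6.92) belong to families of near-identical copies, so the assignment between them is uncertain. Gabrp, a GABA receptor subunit of secretory epithelium, rose by 7.48 (SE 0.42, adjusted p = 3.61e-12), and Crisp1 by 6.91 (SE 0.60, adjusted p = 1.49e-08). All 17 macrophage genes rose, 17 over the list alone, led by Gpnmb at 5.13 (SE 0.65), Trem2 at 3.72 (SE 0.46), Lyz2 at 3.57 (SE 0.48) and Mrc1 at 3.19 (SE 0.48), with camera adjusted p = 1.06e-08 and adjusted p = 0.34 with an estimated correlation. In the lymphocyte list 17 of 18 rose, 17 over the list alone, among them Igkc at 4.08 (SE 0.63) and Cd2 at 3.84 (SE 0.48), with adjusted p = 0.34 with an estimated correlation. Neutrophil genes rose in 2 of 6, also over the list alone: Csf3r 2.26 (SE 0.22) and Mmp9 1.71 (SE 0.27), with S100a9 at 1.09 (adjusted p = 0.0565).

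Proliferation genes rose in 15 of 16, 15 over the list alone, with the cycling marker Mki67 at 2.60 (SE 0.29), Bub1 at 2.30 (SE 0.35) and Top2a at 2.26 (SE 0.27), camera adjusted p = 6.05e-05 and adjusted p = 0.34 with an estimated correlation. Interferon response genes rose in 10 of 12 and fell in 1, with the same counts over the list alone: Zbp1 2.42 (SE 0.35), Oasl2 1.54 (SE 0.27) and Irf7 1.32 (SE 0.23), camera adjusted p = 0.0246 and adjusted p = 0.6 with an estimated correlation. Immediate early genes rose in 12 of 14, 12 over the list alone, with Atf3 at 3.21 (SE 0.44), Klf6 at 2.19 (SE 0.18), Egr1 at 1.77 (SE 0.42) and Junb at 1.67 (SE 0.23), camera adjusted p = 0.000814 and adjusted p = 0.34 with an estimated correlation. Podocyte genes rose in 7 of 8, 7 over the list alone, with Wt1 at 1.22 (SE 0.16) and Synpo at 1.18 (SE 0.23), camera adjusted p = 0.023 and adjusted p = 0.34 with an estimated correlation.

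Proximal tubule and fatty acid oxidation genes fell. Bulk RNA does not tell lower expression per cell from fewer proximal cells. In the single-cell libraries proximal cells were 29.9% of the injured and 79.6% of the uninjured kidney. Within those cells the fatty acid list had a median log2 ratio of 0.07 against 0.09 for all genes, and the proximal list -0.12. The single-cell libraries set injured against uninjured rather than contralateral kidney, in sorted live cells and without replicates. They therefore do not settle the bulk fall. Slc22a8, an organic anion carrier, fell by -2.10 (SE 0.75, adjusted p = 0.0178), Miox by -2.06 (SE 0.74), Slc13a3 by -2.0 (SE 0.73) and Cyp4b1 by -1.97 (SE 0.58). In all 13 of 22 proximal genes fell, 16 over the list alone and 22 without the heart-profile libraries (median -1.64, camera adjusted p = 0.000814, adjusted p = 0.615 with an estimated correlation). Fatty acid oxidation fell in 17 of 20, 19 over the list alone, with Acaa1b at -1.91 (SE 0.66), Ehhadh at -1.58 (SE 0.52), Acads at -1.51 (SE 0.14) and Hadh at -1.48 (SE 0.16), camera adjusted p = 3.3e-08 and adjusted p = 0.0992 with an estimated correlation. The largest falls outside the lists were in Akr1c18 at -2.88 (SE 0.59), Cyp4a14 at -2.87 (SE 0.95), Cyp2d12 at -2.72 (SE 0.77), Esm1 at -2.45 (SE 0.43), Apom at -2.33 (SE 0.69), Rhov at -2.33 (SE 0.59) and Hpd at -2.33 (SE 0.65). The pseudogenes Gm28439 (-6.89) and Gm20390 (-4.16) have close copies and are uncertain.

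Distal convoluted tubule genes fell in 4 of 6, 5 over the list alone, with the calcium binders Pvalb at -2.46 (SE 0.45) and Calb1 at -1.74 (SE 0.72) and the ligase adaptor Klhl3 at -1.28 (SE 0.26), camera adjusted p = 0.0414 and adjusted p = 0.464 with an estimated correlation. Of 8 loop of Henle genes only Egf fell, by -1.70 (SE 0.54), 1 also over the list alone, while Umod stood at -0.64 (SE 0.77, adjusted p = 0.482). None of 13 collecting duct genes passed, 0 over the list alone (median -0.28), where Avpr2 stood at -0.84 (SE 0.60). Endothelial Kdr fell by -0.98 (SE 0.18) and Plvap by -0.82 (SE 0.15), 2 of 12 and 2 over the list alone. Cholesterol synthesis fell in 6 of 15 genes, 4 over the list alone, with Cyp51 at -1.28 (SE 0.37). No adipocyte, erythroid or sex-linked gene passed, 0 in each list alone: Lep stood at 2.29 (adjusted p = 0.0664), Hbb-bs at -0.75 (adjusted p = 0.123) and Ddx3y at 0.18 (adjusted p = 0.232). From the adrenal cortex list only Star was measured, and it rose by 0.66 (SE 0.19, adjusted p = 0.00438), so that list has no test of its own.

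**Figure D2:**
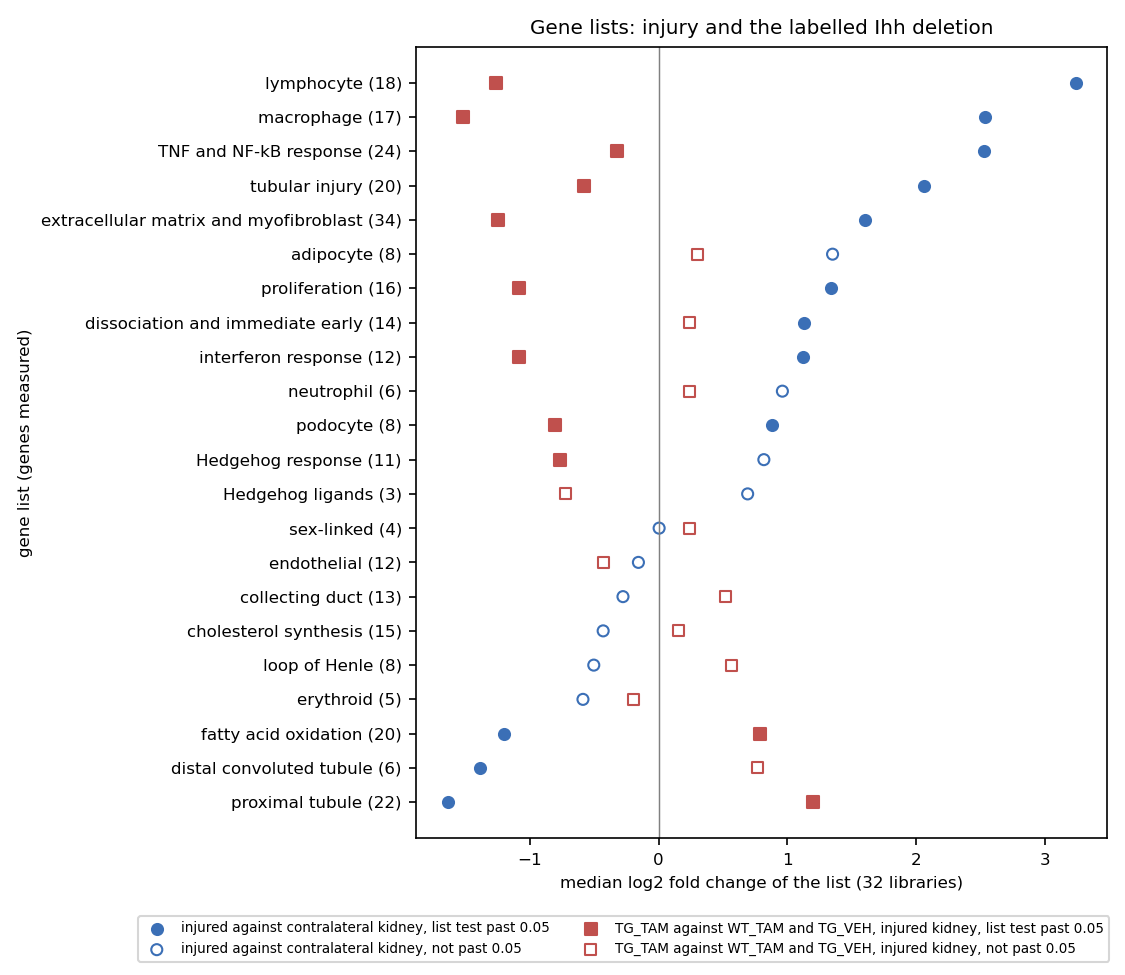
Median log2 fold change of each gene list in the bulk comparisons, for all 32 libraries.

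Injured kidneys labelled Ihh-deleted were set against injured kidneys of the 2 intact arms (n = 4 against 8 libraries). Cx3cr1, the fractalkine receptor of resident macrophages, fell by -2.80 (SE 0.39, adjusted p = 0.000741), from 98.2 (SD 43.1) CPM in the wild-type tamoxifen and 43.1 (SD 27.8) CPM in the floxed vehicle arm to 8.04 (SD 5.49) CPM. Ppara, the regulator of fat burning, rose by 1.36 (SE 0.26, adjusted p = 0.004). Col1a1 stood at -2.05 (SE 0.69, adjusted p = 0.0569), and fell without the heart-profile libraries (-2.04, adjusted p = 0.00104).

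Counts for this comparison moved with single libraries. In all 1657 genes passed, 892 up and 765 down, or 53.8% up, and 6539 without the heart-profile libraries, 3609 up and 2930 down, with every one of the 1657 among them. RLE factors in the same fit gave 684 up and 842 down, 44.8% up, and DESeq2, which changes test and scaling, 1102 up and 1770 down, 38.4% up. Leaving out labelled-deleted library 1, 2, 3 or 4 gave 698, 306, 143 or 3038 genes, leaving out wild-type tamoxifen library 1 or 2 gave 856 or 858, and leaving out floxed vehicle library 4 gave 704. Against the wild-type tamoxifen arm alone 2082 passed, 970 up and 1112 down, and 6797 without the heart-profile libraries. Against the floxed vehicle arm alone edgeR's quasi-likelihood test called 0, with 2772 genes at an unadjusted p under 0.05, and 2881 passed without the heart-profile libraries; DESeq2 was not run on that pair.

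Hedgehog response genes fell in 2 of 11, and in 6 adjusted over the list alone (median -0.77, camera adjusted p = 0.00386, adjusted p = 0.136 with an estimated correlation). Gli1 stood at -1.34 (SE 0.45, adjusted p = 0.0585), Hhip at -2.53 (SE 0.84, adjusted p = 0.0547), Gli3 at -0.99 (SE 0.51) and Ptch1 at -0.12 (SE 0.20, adjusted p = 0.707). Without the heart-profile libraries Gli1 fell by -1.32 (adjusted p = 0.00953) and Hhip by -2.51 (adjusted p = 0.00782). None of the ligands passed, 0 over the list alone: Dhh -0.97 (SE 0.40, adjusted p = 0.113), Ihh -0.73 and Shh -0.63 (SE 0.75, adjusted p = 0.604). Dhh fell in the kidney-profile libraries (adjusted p = 0.0256).

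Matrix genes fell in 5 of 34, in 20 adjusted over the list alone and in 28 without the heart-profile libraries (median -1.25, camera adjusted p = 2.15e-08, adjusted p = 0.413 with an estimated correlation). Col3a1 stood at -1.92 (SE 0.75, adjusted p = 0.0953), Col1a2 at -1.68 (SE 0.56, adjusted p = 0.0556), Timp1 at -1.65 (SE 0.62, adjusted p = 0.082) and Acta2 at -0.85 (SE 0.54, adjusted p = 0.297), and all 4 fell in the kidney-profile libraries (adjusted p = 0.000453, 0.000469, 0.00876 and 0.00854). Outside the list Sfrp4, a secreted Wnt modulator, fell by -2.19 (SE 0.61), and Gucy1a1, a nitric oxide sensor of mural cells, by -1.94 (SE 0.46).

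Macrophage genes fell in 6 of 17, in all 17 over the list alone (median -1.52, camera adjusted p = 2.38e-09, adjusted p = 0.202 with an estimated correlation). Ccr2, the receptor that recruits monocytes, fell by -2.04 (SE 0.42, adjusted p = 0.00587), C3ar1 by -2.29 (SE 0.58, adjusted p = 0.017), Gpr34 by -2.31 (SE 0.74, adjusted p = 0.0471) and Siglec1 by -2.01 (SE 0.62, adjusted p = 0.0403). Gpnmb stood at -2.09 (SE 0.89, adjusted p = 0.12) and Trem2 at -2.0 (SE 0.66, adjusted p = 0.0537). Interferon genes fell in 6 of 12, 12 over the list alone, with Irf7 at -1.47 (SE 0.36) and Oasl2 at -1.45 (SE 0.42), and adjusted p = 0.202 with an estimated correlation. Proliferation genes fell in 5 of 16, 11 over the list alone, with the replication factors Mcm6 at -2.05 (SE 0.62) and Mcm5 at -1.27 (SE 0.24) and with Cdk1 at -1.40 (SE 0.39), and adjusted p = 0.202 with an estimated correlation. Ighv7-3 (-3.75) is an immunoglobulin segment with close copies.

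Among TNF response genes Tnf stood at -1.21 (SE 0.62, adjusted p = 0.199), Cxcl1 at 1.70 (SE 0.62, adjusted p = 0.0751) and Cxcl2 at 1.09 (SE 0.54, adjusted p = 0.179), and 1 of 24 list genes fell, 1 over the list alone (median -0.32, camera adjusted p = 0.0217, adjusted p = 0.582 with an estimated correlation). Without the heart-profile libraries Cxcl1 rose by 1.70 (adjusted p = 0.0158). In the tubular injury list 1 of 20 fell, 1 over the list alone, with Lcn2 at -0.67 (SE 0.39, adjusted p = 0.254), Havcr1 at -1.07 (SE 0.85, adjusted p = 0.417) and adjusted p = 0.202 with an estimated correlation. Within the labelled-deleted arm alone injury raised 22 of 24 TNF genes, 23 over the list alone, and 3 of 34 matrix genes, 1 over the list alone and 16 without the heart-profile libraries. The intact arms raised 24 (wild-type tamoxifen) and 28 (floxed vehicle) matrix genes, and 32 and 33 without those libraries. Fewer genes passed over all in the labelled-deleted arm, 2360 against 7031 and 7636, or 5953 against 10677 and 11200, so these counts alone do not set matrix genes apart.

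Fatty acid oxidation genes rose in 6 of 20, in 9 over the list alone and in 17 without the heart-profile libraries (median 0.79, camera adjusted p = 7.94e-08, adjusted p = 0.202 with an estimated correlation). Acadm, the medium-chain dehydrogenase, rose by 1.27 (SE 0.20, adjusted p = 0.0012). Proximal tubule genes rose in 1 of 22, 1 over the list alone, and in 22 without the heart-profile libraries (median 1.20, camera adjusted p = 0.000422, adjusted p = 0.582 with an estimated correlation), where Pck1 stood at 2.27 (SE 0.91, adjusted p = 0.102) and Slc22a7 at 2.06 (SE 0.96, adjusted p = 0.154). The largest rises were in Ceacam2 at 3.31 (SE 0.83), Eif3j2 at 3.07 (SE 0.89), Tmem252 at 2.89 (SE 0.72), Akr1c18 at 2.70 (SE 0.81), Neurog2 at 2.60 (SE 0.81), Methig1 at 2.52 (SE 0.78) and Osgin1 at 1.91 (SE 0.49). The pseudogenes Gm28439 (6.81) and Gm13502 (6.28) have close copies, and Gm2223 had 0 counts in every intact injured library, so no fold is given.

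Podocyte genes fell in 4 of 8, 4 over the list alone, with Cdkn1c at -0.83 (SE 0.23) and Wt1 at -0.81 (SE 0.24), and adjusted p = 0.202 with an estimated correlation. Stress genes Hspa1a at 1.35 (SE 0.37), Dusp1 at 1.24 (SE 0.34) and Ier3 at 1.05 (SE 0.27) rose, 3 of 14 immediate early genes and 3 over the list alone. No lymphocyte gene passed, 0 over the list alone (median -1.26, camera adjusted p = 1.24e-05, adjusted p = 0.411 with an estimated correlation). Uty, on the Y chromosome, rose by 0.29 (SE 0.09) and was present in every library.

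**Figure D3:**
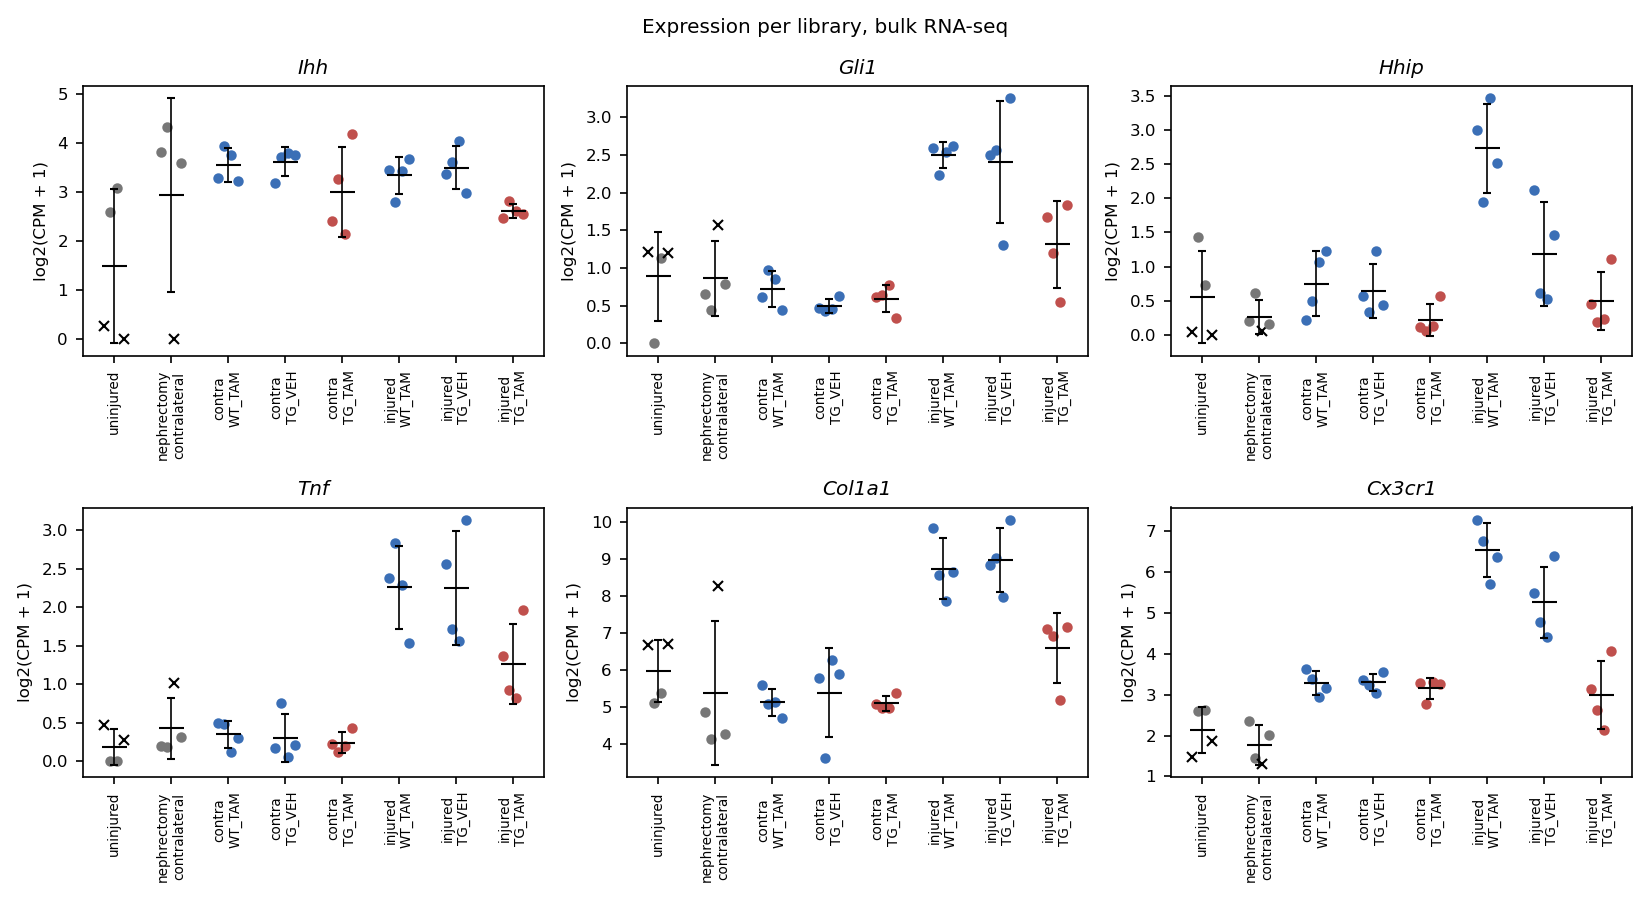
CPM of named genes in each bulk library, by group.

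In the contralateral kidney, which was not made ischaemic, no gene passed between the libraries labelled Ihh-deleted and the intact arms (n = 4 against 8). EdgeR's quasi-likelihood test called 0 genes, with 720 at an unadjusted p under 0.05, and DESeq2 called 39, of which 4 rose and 35 fell. Without CONTRA_TG_VEH library 2 or 3 the count was 1 or 3. In the kidney-profile libraries 1 gene passed, Gm29216 at 9.16 (adjusted p = 0.0199), a value carried by CONTRA_TG_TAM library 3 alone, and DESeq2 called 87. Lcn2 stood at -1.88 (SE 0.44, adjusted p = 0.323), Hhip at -1.91 (SE 0.89), Il6 at -1.89 (SE 0.74), Havcr1 at -1.50 (SE 0.88), Col1a1 at -0.30 (SE 0.63), Tnf at -0.59 (SE 0.72) and Gli1 at -0.02 (SE 0.47). By size alone, with no change claimed, Gm12896 stood at 2.18 (SE 0.54), Irx4 at -2.72 (SE 1.99), Hist1h2ai at -2.05 (SE 0.80) and Serpina3f at -1.92 (SE 0.96). Tubular injury genes shifted down as a list (median -0.42, camera adjusted p = 7.45e-05, adjusted p = 0.193 with an estimated correlation), with 0 genes over all and 1 over the list alone. Interferon genes also shifted down (median -0.42, camera adjusted p = 0.0012, adjusted p = 0.986 with an estimated correlation), with 0 genes over the list alone, and so did macrophage genes (median -0.48, camera adjusted p = 0.0138, adjusted p = 0.986 with an estimated correlation), with 0 over the list alone. Sex-linked genes shifted up (median 0.18, camera adjusted p = 0.012, adjusted p = 0.557 with an estimated correlation), with 1 over the list alone.

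Deletion by kidney interaction, the deletion effect in the injured minus that in the contralateral kidney, picked out Cx3cr1 again. Cx3cr1 stood at -2.63 (SE 0.49, adjusted p = 0.0194). Vangl2, a planar polarity protein, stood at -1.29 (SE 0.25, adjusted p = 0.0199), the growth factor antagonist Spry1 at -1.40 (SE 0.34, adjusted p = 0.0447), Zeb2 at -1.37 (SE 0.33), Wdr86 at -2.34 (SE 0.51), Tril at -1.62 (SE 0.34), Adamtsl1 at -1.41 (SE 0.35), Scarf2 at -1.34 (SE 0.30) and Plppr3 at -1.28 (SE 0.32). In the other direction stood Ndufa4 at 2.00 (SE 0.42), Ndufa13 1.98 (SE 0.46), mt-Co3 1.95 (SE 0.44), Uqcrb 1.92 (SE 0.44) and Atp5j 1.86 (SE 0.41), with the glutamine carrier Slc38a3 at 2.09 (SE 0.45) and Acadm at 1.41 (SE 0.29). Gli1 stood at -1.32 (adjusted p = 0.296), Col1a1 at -1.74 (adjusted p = 0.323), Tnf at -0.62 (adjusted p = 0.769) and Ihh at -0.27 (adjusted p = 0.92). Hedgehog response genes fell in 1 of 11, 2 over the list alone (camera adjusted p = 0.00984, adjusted p = 0.182 with an estimated correlation). Matrix genes passed in 0 of 34, 3 over the list alone (camera adjusted p = 1.39e-06, adjusted p = 0.59 with an estimated correlation).

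That interaction held 167 genes, 128 up and 39 down, or 76.6% up, and 2834 without the heart-profile libraries, 1824 up and 1010 down, or 64.4% up. Of the 167, genes that rose had a median transcript length of 1380 bases and those that fell 2380, against 1780 for all tested. Once each library's trend on length was taken out, 82% of the 167 and 86.7% of the 2834 stayed. Length can therefore account for part of these calls. RLE factors gave 65 up and 29 down (69.1% up), and DESeq2 398 up and 303 down (56.8% up), and in the kidney-profile libraries 2016 up and 1717 down (54.0%), with RLE factors giving 1484 and 1247 (54.3%). Without IRI_TG_TAM library 1, 2, 3 or 4 the count was 41, 4, 7 or 841. Leaving out IRI_WT_TAM 1 or 2 gave 23 or 33, and IRI_TG_VEH 2, 3 or 4 gave 28, 315 or 29. Leaving out CONTRA_TG_TAM 1, 2, 3 or 4 gave 41, 25, 16 or 5, CONTRA_WT_TAM 1 to 4 gave 95, 27, 40 and 36, and CONTRA_TG_VEH 3 or 4 gave 275 or 103.

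Averaged over both kidneys, Cx3cr1 fell by -1.49 (SE 0.26, adjusted p = 0.0398), Ifitm1, an interferon-induced membrane protein, by -1.02 (SE 0.21, adjusted p = 0.0494), Tipin by -0.57 (SE 0.10, adjusted p = 0.0398) and Anxa5 by -0.46 (SE 0.09, adjusted p = 0.0398), for 8 libraries labelled Ihh-deleted against 16. The value of Cx3cr1 comes from the injured kidney, since it stood at -0.17 (SE 0.34) in the contralateral kidney. Lcn2 stood at -1.27 (SE 0.29, adjusted p = 0.0779) and fell in the kidney-profile libraries (adjusted p = 0.012). Hhip stood at -2.22 (SE 0.61, adjusted p = 0.11). In all 12 genes passed, 5 up and 7 down (41.7% up), against 5 up and 4 down with RLE factors (55.6%), and 2747 passed without the heart-profile libraries, 1531 up and 1216 down. The count was 909 without IRI_TG_TAM library 4, 94 without IRI_TG_VEH 3, 28 without CONTRA_TG_VEH 2 and 1 without CONTRA_WT_TAM 1. It was 0 without each of IRI_TG_TAM 1, 2 and 3, IRI_WT_TAM 1 and 2, IRI_TG_VEH 1, 2 and 4, CONTRA_TG_TAM 1 to 4, CONTRA_WT_TAM 2, 3 and 4, and CONTRA_TG_VEH 1, 3 and 4. Macrophage genes fell in 1 of 17, 12 over the list alone (median -0.99, camera adjusted p = 1.96e-12, adjusted p = 0.156 with an estimated correlation), and interferon genes in 0 of 12, 11 over the list alone, with adjusted p = 0.12 with an estimated correlation.

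Against uninjured controls (n = 8 injured libraries of the intact arms against 4), 14 of 20 tubular injury genes rose, 15 over the list alone (camera adjusted p = 1.18e-05, adjusted p = 0.083 with an estimated correlation). Lcn2 rose by 4.21 (SE 0.51, adjusted p = 5.22e-07), with 4.21 (adjusted p = 0.000323) against the 2 kidney-profile controls alone. Havcr1 rose by 4.52 (SE 1.20, adjusted p = 0.00286) and by 2.75 (adjusted p = 0.034) against those 2, and Tnf by 3.34 (SE 0.81, adjusted p = 0.0014), with 0 CPM in both of them. Cxcl10 rose by 5.37 (SE 1.05, adjusted p = 0.000155) and by 5.0 (adjusted p = 0.0126). Gli1 rose by 1.28 (SE 0.49, adjusted p = 0.0318) and by 1.79 (adjusted p = 0.04) and Col1a1 by 2.14 (SE 0.70, adjusted p = 0.0127) and by 3.34 (adjusted p = 0.000321). Hhip rose by 3.59 (SE 1.14, adjusted p = 0.0113) only with the heart-profile controls, at 1.52 (adjusted p = 0.338) without them.

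In that comparison 8402 genes passed, 4211 up and 4191 down, and 8020 without the heart-profile libraries, 4154 up and 3866 down, of which 4611 were shared and where the median of all genes was shifted by 0.14. The largest falls were heart genes that mark the 2 heart-profile controls: Casq2 -11.97 (SE 1.77), Ryr2 -10.06 (SE 1.48), Smpx -9.68 (SE 1.38), Trdn -9.35 (SE 1.30) and Mylk3 -9.12 (SE 1.32), with Casq2 at -1.85 (adjusted p = 0.482) without them. TNF genes rose in 22 of 24, 22 over the list alone (median 2.50, camera adjusted p = 1.14e-12, adjusted p = 0.083 with an estimated correlation), and fatty acid oxidation fell in 16 of 20, 16 over the list alone (median -2.0, adjusted p = 0.0314 with an estimated correlation), and in 19 without the heart-profile libraries (median -1.57, adjusted p = 0.132 with an estimated correlation), with Acaa2 at -2.96 (SE 0.33) and Acadl at -2.68 (SE 0.31). Macrophage Mpeg1 rose by 3.91 (SE 0.44), Cd74 by 3.64 (SE 0.43) and Cx3cr1 by 3.68 (SE 0.44), 14 of 17 list genes and 16 over the list alone, with adjusted p = 0.36 with an estimated correlation. Proximal genes fell in 1 of 22, 1 over the list alone, but in all 22 against the kidney-profile controls (median -2.0, adjusted p = 0.132 with an estimated correlation), where Slc22a7 fell by -2.94 (adjusted p = 1.35e-05). Ighg1 had 0 counts in all 4 controls and 117 (SD 109.7) CPM in injured wild-type tamoxifen kidneys, so no fold is given.

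Contralateral kidneys of the intact arms differed from uninjured controls (n = 8 against 4) mostly by what the 2 heart-profile controls contain. Myh6 fell by -15.96 (SE 2.31) and Casq2 by -11.49 (SE 1.72), but Myh6 stood at -1.96 (adjusted p = 0.83) against the kidney-profile controls. Heat-shock gene Hspa1a fell either way, by -2.33 (SE 0.38, adjusted p = 0.000183) and by -2.84 (adjusted p = 1.94e-05), as did Hspa1b by -2.44 (SE 0.53, adjusted p = 0.00147) and -3.20 (adjusted p = 0.000515). In all 5257 genes passed, 1682 up and 3575 down, and 55 passed without the heart-profile libraries, 28 up and 27 down and a median shift of 0.109 over all genes, of which 41 were shared. Of the 32 libraries, leaving out uninjured control library 1, 3 or 4 gave 2094, 8411 or 2124. Without the heart-profile libraries and CONTRA_TG_VEH library 2 the count was 160. Adipocyte genes fell in 4 of 8, 7 over the list alone (median -3.00, adjusted p = 0.713 with an estimated correlation), with Lep at -6.61 (SE 1.44), but in 0 and 1 without the heart-profile libraries. Ihh stood at 2.15 (SE 0.98, adjusted p = 0.0958) and at 0.76 (adjusted p = 0.656) against the kidney-profile controls, Col1a1 at -1.08 (adjusted p = 0.168) and at 0.13 (adjusted p = 0.994), Lcn2 at 0.65 and at 0.67, and Tnf at -0.06.

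Immediate early and neutrophil genes separated the contralateral kidney after injury from the kidney left after nephrectomy (n = 8 against 4). The nephrectomy and uninjured libraries belong to no injury arm and have no recorded harvest time. Genotype, treatment and time can therefore differ along with the operation and cannot be told apart from it. Atf3 fell by -4.53 (SE 0.61, adjusted p = 6.29e-05) in the contralateral kidney, Egr1 by -2.75 (SE 0.59, adjusted p = 0.00378), Btg2 by -2.44 (SE 0.38, adjusted p = 0.000277) and Fosb by -2.42 (SE 0.71, adjusted p = 0.0326). Cxcl1 fell by -4.61 (SE 0.66, adjusted p = 0.000137), Cxcl2 by -4.16 (SE 0.63, adjusted p = 0.000239) and Tnfaip3, the NF-kB feedback gene, by -1.87 (SE 0.34, adjusted p = 0.00102). S100a9, an alarmin of neutrophils, fell by -2.66 (SE 0.64, adjusted p = 0.00891) and S100a8 by -2.32 (SE 0.55, adjusted p = 0.00744). Without the heart-profile library Atf3 stood at -3.05, Egr1 at -2.75, Cxcl1 at -4.95 and S100a9 at -2.71, all passing. Cx3cr1 rose by 1.68 (SE 0.38, adjusted p = 0.00549) and the interferon gene Ifi44 by 1.33 (SE 0.30, adjusted p = 0.0052).

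Of 14 immediate early genes 13 fell, 13 over the list alone (median -2.05, camera adjusted p = 6.43e-27, adjusted p = 0.00274 with an estimated correlation), and of 6 neutrophil genes 5 fell, 5 over the list alone (median -1.97, adjusted p = 0.00402 with an estimated correlation). TNF genes fell in 7 of 24, 8 over the list alone, with adjusted p = 0.301 with an estimated correlation. In all 1389 genes passed, 215 up and 1174 down, and 777 without the heart-profile libraries, 289 up and 488 down (37.2% up), or 47.2% up with DESeq2, of which 434 were shared with the 1389. Leaving out nephrectomy library 3 gave 261. The largest falls, Mb at -16.58 (SE 2.59), Myh6 at -14.86 (SE 2.25), Xirp2 at -12.14 (SE 2.00) and Tnnt2 at -10.55 (SE 1.67), are heart genes of nephrectomy library 3, and Myh6 stayed at -8.46 without it because library 1 held a trace.

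Nephrectomy kidneys against uninjured controls (n = 4 against 4) share the nephrectomy libraries with the comparison above. Of 14 immediate early genes 1 rose, with 11 up and 2 down over the list alone and adjusted p = 0.129 with an estimated correlation. Plk3, a stress-induced kinase, rose by 4.57 (SE 0.68, adjusted p = 0.0017) and by 4.14 (adjusted p = 0.017) without the heart-profile libraries. The orphan receptor Nr4a3 rose by 4.24 (SE 0.84, adjusted p = 0.0165) and by 4.36 (adjusted p = 0.0362), Slc25a25 by 2.75 (SE 0.62) and by 2.31 (adjusted p = 0.017), and Zfp128 fell by -1.01 (SE 0.23) and -1.07 (adjusted p = 0.0436). Cxcl10 at 5.11 (SE 1.08), Gdf15 at 4.49 (SE 0.89), S100a8 at 4.42 (SE 0.87), Nr4a2 at 2.96 (SE 0.55), Tnfaip3 at 2.48 (SE 0.46) and Junb at 2.17 (SE 0.41) rose with all libraries only, as Aplnr fell by -2.62 (SE 0.46) and Adora2a by -1.68 (SE 0.33). In all 54 genes passed, 49 up and 5 down (90.7% up), against 155 up and 52 down with DESeq2 (74.9%), and 31 without the heart-profile libraries, 23 up and 8 down, of which 13 were shared. The count was 17, 5258 or 25 without nephrectomy library 2, 3 or 4 and 15, 1547 or 21 without uninjured library 1, 3 or 4. Neutrophil genes rose in 2 of 6, 5 over the list alone (median 2.82, adjusted p = 0.00944 with an estimated correlation), and TNF genes in 6 of 24, 10 over the list alone, with adjusted p = 0.226 with an estimated correlation.

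In the single-cell libraries immune cells made up 39.4% (37.6 to 41.1) of 3058 cells of the injured kidney and 2.9% (2.06 to 3.96) of 1310 cells of the uninjured kidney. Proximal tubule cells, the segment most exposed to ischaemia, were 29.9% (28.2 to 31.5) against 79.6% (77.3 to 81.8). B cells were 10.5% (9.43 to 11.6) against 0.229% (0.0473 to 0.668), T cells 10.5% (9.43 to 11.6) against 0.84% (0.42 to 1.5), dendritic cells 9.45% (8.44 to 10.5) against 0.687% (0.315 to 1.3) and macrophages or monocytes 8.93% (7.94 to 9.99) against 1.15% (0.642 to 1.88). Endothelial cells were 7.23% (6.33 to 8.2) against 1.91% (1.24 to 2.8), and fibroblasts or mural cells 3.43% (2.82 to 4.14) against 0.534% (0.215 to 1.1). Loop of Henle cells, at 5.07% (4.32 to 5.91) against 4.5% (3.45 to 5.77), collecting duct principal cells, at 4.45% (3.74 to 5.24) against 3.44% (2.52 to 4.57), and intercalated cells, at 2.91% (2.34 to 3.57) against 2.44% (1.68 to 3.43), had overlapping intervals. Unnamed clusters held 7.68% (6.77 to 8.69) against 4.66% (3.58 to 5.94). The immune share leaves out an unnamed cluster of 57 and 1 cells with Igkc and Ighm among its leading genes. The endothelial share leaves out an unnamed cluster led by Cldn5 with 8 raised endothelial markers, at 1.93% (1.47 to 2.48) against 2.14% (1.42 to 3.07), and counting it would narrow that difference. With a stricter cell filter proximal cells were 14.6% against 61.0% and immune cells 48.8% against 6.62%, and the libraries differ in median mitochondrial share, 5.97% against 23.6%. Each condition is 1 library, so no test was made, and the 95% intervals cover counting error only.

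**Figure D4:**
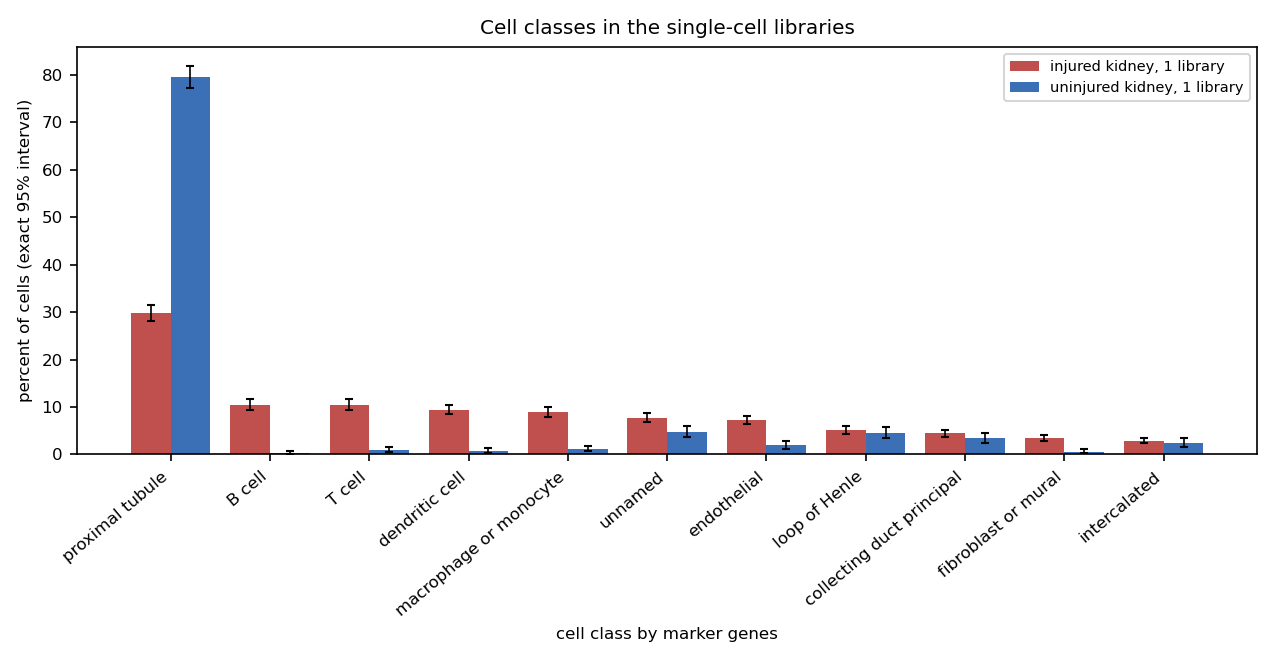
Share of cells per class in the injured and the uninjured single-cell library, with exact 95% intervals of counting error.

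Ihh lay in proximal tubule cells with 12 of 25 UMIs in the injured and 25 of 28 in the uninjured kidney, and 11 more in unnamed injured-kidney cells. Such counts do not place it, since proximal cells held most UMIs of the uninjured library and intercalated cells stood at 15.1 CPM there on 2 UMIs. In proximal cells it was at 5.08 against 7.54 CPM, ratio 0.673 (0.308 to 1.39). Over all cells Ihh was 3.23 against 6.93 CPM, ratio 0.47 (0.260 to 0.828), a ratio that also reflects the smaller share of proximal cells. Tnf had 25 UMIs in the injured kidney, 10 in macrophages or monocytes, 7 in dendritic cells, 7 in T cells and 1 in B cells, and was not listed in the uninjured table. Lcn2 had 442 UMIs against 4, of which 307 lay in loop of Henle cells, whose defining genes include it. Ptch1 had 84 UMIs against 29, of which 28 and 7 in intercalated cells, too few cells for a comparison. Col1a1 and Acta2, which define fibroblasts or mural cells, had 96.4% and 97.4% of their injured-kidney UMIs there, but largely in different clusters of that class. The cluster led by Tagln and Acta2 held 318 Acta2 and 4 Col1a1 UMIs of the injured kidney. That led by Mgp and Col3a1 held 58 and 235. Dhh had 17 UMIs in the injured kidney, 13 of them in unnamed cells, and Gli1 and Hhip were not listed in either table.

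Proximal tubule cells and loop of Henle cells were the only classes with enough cells for a comparison of expression. In proximal cells the vitamin D hydroxylase Cyp24a1 had 15 UMIs against 89, ratio 0.236 (0.127 to 0.411), and Ehhadh, of peroxisomal fat burning, 0.448 (0.358 to 0.558), though at 1.11 in 1 of 5 proximal clusters, with Cfb at 0.391, Serinc3 at 0.432 and Cyp4a12a at 0.448. The higher genes there were Ighm at 495 (88.3 to 19600), Ccl5 at 96.4, Igkc at 51.9 (35.7 to 78.5), Cd74 at 12 (10.4 to 13.9) and Tmsb4x at 11.9, all far more abundant in leukocytes, so free RNA in the droplets can produce them. In loop cells S100a6 had 464 UMIs against 1, ratio 206 (36.9 to 8170), and 2200002D01Rik had 77 UMIs against 0. Clu, a secreted chaperone of injured tubules, stood at 24 (15.1 to 40.7), Tmsb4x at 27.8 and Igkc at 40.9. In the other cells of the injured library Tmsb4x and Igkc stood at 8090 and 25700 CPM, against 1020 and 429 CPM in loop cells. Free RNA can therefore produce their ratios too. Lower in loop cells were Nccrp1 at 0.0724, Slc12a3 at 0.0918 (0.0463 to 0.169), Lpl at 0.218, Ppp1r1b at 0.313 and Ckb at 0.314. Slc12a3 is a marker of the distal convoluted tubule, for which no class was named. A change in cell mix within this class was not told apart from one in expression. By list, proximal genes stood at a median log2 ratio of -0.12 in proximal cells against 0.09 for all genes, at percentile 0.00 of 10000 matched lists, cholesterol synthesis at -0.17 (percentile 0.23), fatty acid oxidation at 0.07 (percentile 37.4) and immediate early genes at 0.26 (percentile 95.2). These percentiles rank lists within 1 pair of libraries and cover no spread between animals.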

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

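The splits of injury and of nephrectomy against uninjured kidneys over the 29 kidney-profile libraries were planned before they were run. The other splits, or the way they are counted, and the tests of other explanations were chosen after the results were seen.

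Heart genes in place of kidney genes were found in uninjured control libraries 1 and 4 and in nephrectomy library 3. If heart RNA had been mixed into kidney samples, kidney genes would remain in quantity. Their highest share in these libraries was 0.111% of the median of the other libraries of the same group, which excludes mixing as the cause. A library made from another tissue predicts that kidney genes are nearly gone, and 7 of 8 kidney genes were under 1% of their usual level in all 3. The libraries therefore behave as heart tissue under a kidney label, and whether tissue or label was exchanged cannot be read from the files. Nephrectomy library 1 holds a trace, with heart genes at 0.0652% of counts and Myh6 at 314 CPM.

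The weaker matrix and macrophage expression in injured kidneys labelled Ihh-deleted was set against 2 other explanations. A trend of counts on transcript length that differs between libraries is excluded as the whole cause, since 94.6% of the 1657 calls stayed once each library's trend was taken out. A smaller injury response as a whole predicts that matrix and TNF genes shrink by the same proportion. The deletion change against either intact arm was set on the injury response of the other. With wild-type tamoxifen as control and floxed vehicle as injury arm, the matrix slope minus the TNF slope was -0.62 (-0.91 to -0.34). With these arms exchanged it was -0.25 (-0.51 to 0.01). The smaller value of -0.25 has an interval that reaches 0, so a milder injury in those 4 kidneys cannot be told from an effect of the deletion.

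Immediate early genes were higher after nephrectomy than in the contralateral kidney after injury. The heart-profile library is excluded as the cause, since 13 of 14 genes still passed without it. More blood in the nephrectomy kidneys predicts more erythroid RNA there. In the kidney-profile libraries 5 of 5 erythroid genes were instead higher in the contralateral kidneys, adjusted over the list alone. That argues against more red cells, but these genes do not measure blood leukocytes. Handling after removal was not excluded: 5 of 6 neutrophil genes followed the same pattern when adjusted over the list alone, but that restates the result itself. It stays open for both lists.

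Chance was weighed by regrouping the libraries, with the real grouping counted among the groupings, 100 where that many exist. Regrouping covers these libraries only, since the labels do not say that the columns of a group are separate animals. Where the 2 intact arms are averaged, groupings that only exchange libraries between these arms count as 1. For injury against contralateral kidneys the real grouping alone, 1 of 100, reached its count: 10580 against at most 18 with all libraries, and 12972 against at most 5396 with the kidney-profile libraries. For the deletion in injured kidneys it was again 1 of 100, with 1657 against at most 462 and 6539 against at most 3406, and for the interaction 1 of 100, with 167 against at most 88 and 2834 against at most 489. A chance division of the libraries is therefore unlikely for these counts. Averaged over both kidneys, 2 of 100 groupings reached 12 genes with all libraries, the other with 16. With the kidney-profile libraries 1 of 100 reached 2747, against at most 172. A chance division is unlikely there too. In the contralateral kidney the real count of 0 is reached by 100 of 100 groupings whatever the data, with 16 as the highest other, so it says nothing about chance. With the kidney-profile libraries 24 of 100 reached the count of 1, up to 105, so chance is not excluded, and a split calling 105 genes points to a structure of the samples other than the labels.

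For injured against uninjured kidneys 1 of 100 groupings reached the real count with all libraries, 8402 against at most 4078. With the kidney-profile libraries it was 1 of 45, 8020 against at most 3001. For contralateral kidneys after injury against nephrectomy it was 1 of 100, 1389 against at most 1014 and 777 against at most 537. A chance division of the libraries is unlikely for these counts. For contralateral against uninjured kidneys it was 1 of 100 with all libraries, 5257 against at most 5107, where the highest other split keeps both heart-profile controls together. In the kidney-profile libraries 7 of 45 groupings reached the real count of 55, so chance is not excluded. A split calling 3975 genes there points to a structure of the samples other than the labels. For nephrectomy against uninjured kidneys 6 of 35 groupings reached 54, so chance is not excluded, and a split calling 10080 genes follows the heart-profile libraries. With the kidney-profile libraries only 10 groupings exist, 2 of them reaching the real count of 31 with 31 as the highest other, which is too few to tell.

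Single values that stood apart from the other 3 of their group by Dixon's ratio at 0.05 numbered 16 of 120 groups tested, where chance gives about 1 in 20 groups, or 6. Nephrectomy library 3 gave 8 of them: heart genes at 6.2% and kidney genes at 0.00344% of counts, Ptch1 at 28.5, Tnf at 1.03, Havcr1 at 0, Lcn2 at 1.32, Col1a1 at 309 and Acta2 at 130 CPM. Nephrectomy library 4 was shallow, with 8.34 M counts. The others were Hhip at 0.488 CPM in CONTRA_TG_TAM library 4, Ihh at 8.05 CPM in CONTRA_TG_VEH library 1, Shh at 0.396 CPM in CONTRA_TG_VEH library 2, Lcn2 at 18.3 CPM in CONTRA_TG_VEH library 3, and Ptch1 at 61.8 CPM in IRI_TG_VEH library 1. In the uninjured group Shh stood at 2.78 CPM in library 3 and Gli1 at 0 in library 2. Uninjured library 2 held only 0.593 M counts, so that 0 can reflect depth.

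Among the genes whose deletion effect differed most between the injured and the contralateral kidney were Cx3cr1 at -2.63, Wdr86 at -2.34, Tril at -1.62, Adamtsl1 at -1.41, Spry1 at -1.40, Zeb2 at -1.37, Scarf2 at -1.34, Vangl2 at -1.29 and Plppr3 at -1.28. In the other direction stood Slc38a3 at 2.09, Ndufa4 at 2.00, Ndufa13 at 1.98, mt-Co3 at 1.95, Uqcrb at 1.92 and Atp5j at 1.86. The pseudogenes Gm13502 at 11.49, Gm28439 at 8.25, Gm20594 at 3.50 and Gm15387 at 2.62 resemble other transcripts closely, and reads can move between such copies.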

How the results depend on the processing

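The settings that leave out named libraries together, the fit of the injury arms alone and the replicate block were chosen after the results were seen, and the others were planned. The cause of a change was not tested unless stated.

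Leaving out the 3 heart-profile libraries lowered the spread within 2 groups, on which every test draws. The deletion in injured kidneys then had 6539 genes, the interaction 2834, the average over both kidneys 2747 and the contralateral deletion 1, all more than with 32 libraries. Fewer passed for contralateral against uninjured kidneys (55), contralateral against nephrectomy (777) and nephrectomy against uninjured (31). Those contrasts themselves hold the heart-profile libraries, and leaving these out also made their groups smaller. Which of these lowered the counts was not told apart. With RLE factors added these 7 counts, in the same order, were 6460, 2731, 2731, 7, 62, 763 and 25. With DESeq2 added they were 6990, 3733, 3707, 87, 80 and, for nephrectomy against uninjured, 113, with 1221 for contralateral against nephrectomy. Without CONTRA_TG_VEH library 2 as well, the deletion gave 7687 in injured kidneys, 3230 for the interaction, 4199 over both kidneys and 4 in contralateral kidneys, with 160 for contralateral against uninjured, 1300 for contralateral against nephrectomy and 52 for nephrectomy against uninjured. Without uninjured library 2 as well, these were 6670, 2835, 2654, 1 and 10, with 850 for contralateral against nephrectomy and 2 for nephrectomy against uninjured.

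By camera, which sets a list against all other genes, the direction of lists turned without the heart-profile libraries in 17 of 198 cases, given here with the medians, of which 4 kept their own sign. In injured against uninjured kidneys proximal tubule became -2.0, loop of Henle -0.80, collecting duct -0.735 and cholesterol synthesis -0.765. In contralateral against uninjured kidneys loop of Henle became -0.12, collecting duct -0.32, cholesterol synthesis -0.051, proximal tubule 0.033, endothelial 0.41 and macrophage 0.80. In contralateral against nephrectomy kidneys proximal tubule became -0.18, loop of Henle -0.24, distal convoluted tubule -0.25, collecting duct -0.21, cholesterol synthesis -0.24 and matrix 0.61, and in nephrectomy against uninjured kidneys collecting duct became -0.22. Acta2 in contralateral against uninjured kidneys became 0.034 without uninjured library 2 as well.

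The 24 libraries of the injury arms alone gave 6398 genes for the deletion in injured kidneys, 2422 for the interaction and 2319 over both kidneys. Column number within arm as a replicate block gave 1711 genes for the interaction and 12632 for injury, fewer than the 2422 and 12740 of the same 24 libraries without it. DESeq2 on all libraries gave 2872 for the deletion in injured kidneys, 39 in contralateral kidneys, 701 for the interaction, 532 over both kidneys and 207 for nephrectomy against uninjured. No low-count filter gave 966, 1, 37 and 0 for the 4 deletion counts in that order. RLE factors gave 94 for the interaction. The floxed vehicle arm alone as control gave 0 for the deletion in injured kidneys.

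Leaving out 1 library at a time gave 143 to 3038 genes for the deletion in injured kidneys, 0 to 3 in contralateral kidneys, 4 to 841 for the interaction and 0 to 909 over both kidneys. With the kidney-profile libraries these ranges were 3534 to 7584, 0 to 39, 854 to 4842 and 674 to 4678. Each range covers only the libraries that its own contrast compares. It gave 2094 to 8411 for contralateral against uninjured, 261 to 1940 for contralateral against nephrectomy and 15 to 5258 for nephrectomy against uninjured kidneys. Shh in contralateral against uninjured kidneys ran from -1.11 to 3.12, the latter without uninjured library 3. Col1a1 in nephrectomy against uninjured kidneys ran from -1.96, without nephrectomy library 3, to 0.69.

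Injury counts stayed within 1.5 times everywhere: 10606 with RLE factors, 11041 with no filter, 11186 with DESeq2, 11408 with no arm factor, 12230 with the intact arms alone, and 9957 to 10637 leaving out 1 library. Of named genes, RLE factors weakened 7 of 237, no filter 32 of 237 and DESeq2 1 of 236, which also strengthened 9, while leaving out the heart-profile libraries weakened 53 and strengthened 17 of 236. An estimated correlation weakened 83 of 198 list results. The median of all genes in the injury contrast was 0.112 with RLE factors, 0.111 with no filter and 0.113 with DESeq2.

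The stricter cell filter left 2911 cells and moved the proximal share to 14.6% in the injured and 61.0% in the uninjured library and the immune share to 48.8% and 6.62%. Of 35 single-cell values that filter moved 18, and of 18 each Leiden resolution 0.5 moved 6, resolution 2 moved 5 and keeping doublets 0.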

Other observations

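All tests in this part were chosen after the results were seen.

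The 2 intact arms differed from each other in the injured kidney. Set as wild-type tamoxifen minus floxed vehicle (n = 4 against 4), 56 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 up and 50 down, and 392 passed without the heart-profile libraries. Plk3 fell by -3.93 (SE 0.62, adjusted p = 0.00378), with 7.09 to 10.3 CPM against 56.9 to 215 CPM, while the labelled-deleted arm held 61.1 to 275 CPM. S100a8 fell by -4.25 (SE 0.75, adjusted p = 0.00764), S100a9 by -4.96 (SE 0.92, adjusted p = 0.0139), Retnlg by -5.01 (SE 0.97, adjusted p = 0.0193), Il6 by -2.74 (adjusted p = 0.0451) and Crem, a cAMP-responsive factor, by -1.71 (SE 0.21, adjusted p = 0.000267). Cxcl12 rose by 1.48 (SE 0.29, adjusted p = 0.0193). Neutrophil genes fell in 3 of 6, 3 over the list alone (median -2.13, adjusted p = 0.0182 with an estimated correlation and 0.216 without the heart-profile libraries). Cxcl1 shows the same split, at 4.80 to 11.8 CPM in the wild-type tamoxifen arm, 22.3 to 79.3 CPM in the floxed vehicle arm and 3.05 to 118 CPM in the labelled-deleted arm, so a rise of Cxcl1 in the deletion comparison rests on the wild-type arm. In contralateral kidneys the same 2 arms differed in 0 genes, with 1033 at an unadjusted p under 0.05, and DESeq2 was not run on that pair.

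Genes that injury raised were read in the deletion comparison with no library shared. Of 2925 genes raised in the floxed vehicle arm by more than log2 1, 87.4% were lower in the labelled-deleted than in the wild-type tamoxifen injured kidneys (median -0.96 against -0.02 for all genes), 585 fell and 64 rose past an adjusted p of 0.05. Of 1384 genes lowered there by more than log2 1, 5.92% were lower (median 0.69). Of 2969 genes raised so in the wild-type tamoxifen arm, 95.9% were lower than in the floxed vehicle injured kidneys, where 0 fell and 0 rose past that threshold, and 861 of 3634 fell and 3 rose without the heart-profile libraries. With an estimated correlation these lists gave p = 0.0277 and 0.0355 by camera of limma for the first pair, 0.00616 for the raised genes of the other arm and, not passing, 0.07 for the lowered genes of the first pair without the heart-profile libraries. Most genes that injury raised by more than log2 1 were therefore lower in the kidneys labelled Ihh-deleted, beyond matrix genes, which leaves a milder injury open.

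Among the 55 genes that passed between contralateral kidneys and the 2 kidney-profile controls, Hspa1b fell by -3.20, Hspa1a by -2.84, Hsph1 by -1.32 and Dnajb1 by -0.88, all heat-shock genes, and Tsc22d3 by -1.51 and Sgk1 by -1.45, both induced by glucocorticoids. Cry1 fell by -2.15 and Nr1d1 rose by 1.72, opposite arms of the circadian clock, and Srebf1 fell by -1.01. Hspa1a stood at 113 and 130.0 CPM in the 2 kidney-profile controls against 9.98 to 28.1 CPM in contralateral kidneys. Time of day and time from death to freezing are not given in the sources used here. Only 2 control libraries carry the comparison, and uninjured library 2 held just 0.593 M counts. Chance is not excluded for it, since 7 of 45 groupings reached 55 genes, and no list of these themes was tested.

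A cluster left unnamed, led by Fst, Bst1 and Cryab, held 119 cells of the injured and 32 of the uninjured kidney. These were 3.89% (3.23 to 4.64) and 2.44% (1.68 to 3.43) of cells, so the cluster was not confined to injury. Its best class was injured tubule, with 8 raised markers from a list that holds Havcr1 and Lcn2. The name was refused because its 10 leading genes held 0 of these markers and 1 of another class, Aqp1 of the proximal tubule. The cluster held 18 of the 30 Havcr1 UMIs of the injured library and 46 of its 442 Lcn2 UMIs, of which 307 lay in loop of Henle cells. Ihh had 11 UMIs there, 32.5 CPM (16.2 to 58.1) against 5.08 CPM in proximal tubule cells of the same library. Its cells were not assigned to a nephron segment.

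Tnfrsf1a, the TNF receptor of most cells and a member of the TNF list, had 45 UMIs in injured and 26 in uninjured proximal tubule cells, 19.0 (13.9 to 25.5) against 7.84 (5.12 to 11.5) CPM, ratio 2.43 (1.47 to 4.1). In endothelial cells of the injured kidney it was 292 CPM. It was chosen after its values were seen, and each condition is 1 library. Over all cells it was 49.2 against 16.1 CPM, ratio 3.06, so free RNA from other cells can produce the proximal rise.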
